A study of Homo sapiens with 12 samples.

How the data were processed

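The data come from Jurkat cells, an established human CD4-type T cell leukaemia line widely used to study signalling from the T cell receptor. Per the labels, the cells were stimulated with a phorbol ester and ionomycin and their total RNA was taken at 0, 30 and 60 min. A phorbol ester activates protein kinase C and ionomycin carries calcium into the cell, so that together they bypass the T cell receptor. Biotin-labelled antisense RNA was made with an Ambion MessageAmp kit and hybridised to Affymetrix U133 Plus 2 arrays, per the labels' protocols. These arrays read each transcript with sets of short probes placed towards its 3′ end. The titles of the samples give 2 biological replicates at each time and 2 arrays for each RNA sample, which makes 12 arrays from 6 RNA samples. The labels do not say whether the 2 replicates were separate cultures grown on separate days, so p-values measure the spread between these samples. One label lists later times, another a single treatment of a different length, and the extraction protocol describes promoter arrays, whereas the probe sets in the table are those of the U133 Plus 2 array. The group of each sample was taken from its own title and source name.

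The deposited table holds 1 linear signal intensity per probe set and array, and the submitters' processing notes name MAS5. The settings of MAS5 are not given in the sources used here. On the deposited values, the mean signal after trimming 2% at each end lay between 500.06 and 500.07 on all 12 arrays, as global scaling to a target of 500 gives, and the medians ran from 74.83 to 90.22. This scaling was kept, because the trimmed means differed by less than the 10% set for a further normalisation. MAS5 sets 1 array against no other and subtracts a mismatch signal, so its values scatter widely at low brightness. The table carries no detection calls, and the number of arrays limits the precision of every value.

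All values were converted to log2(signal + 20.75), where the offset is 0.25 of the median of all values, 83.00. Fold changes are on this scale and understate the change of dim genes. The 2 arrays of each RNA sample were averaged on the log2 scale and counted as 1 replicate, so n = 2 at each time. Of 54675 probe sets, 62 control probe sets were left out, and a probe set was kept where at least 4 of the 12 arrays lay above their own median, which left 29013. Means of signal are given in MAS5 units with the SD of the 2 replicates.

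The 3 times were compared pairwise with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). All 6 averaged samples entered 1 fit with 3 residual and 4.87 prior degrees of freedom. The tests are two-sided, adjusted p-values are by Benjamini-Hochberg over the probe sets kept, and a change was called at an adjusted p under 0.05. With 2 samples per time an exact permutation test of a single gene cannot reach that threshold, so every call rests on limma's pooling of the spread over genes.

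Probe sets were named from the platform annotation, with symbols updated through gene IDs to a RefSeq table on GRCh38.p14. In this annotation 41097 probe sets have 1 gene, of which 41043 were updated, 1801 have several and 11777 have none. Probe sets without exactly 1 gene are given by their ID. For a gene with several kept probe sets the brightest stands for it, leaving out cross-hybridising _x_at sets where another exists, which gave 12939 genes.

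Before the data were examined, the design, the alternatives, the gene lists and the rule for named genes were fixed. The rule takes, for each comparison, the 12 genes with the largest rise and the 12 with the largest fall among the called genes that moved the same way in both replicates. Members of the fixed lists may be named as examples, called members first. Genes and probe sets named outside this rule were chosen after their values were seen and are said to be so. The 16 lists cover immediate-early transcription factors, feedback inhibitors of MAP kinase and EGR signalling, NF-kappaB genes, cytokines and chemokines, the calcineurin and NFAT axis, T cell activation receptors, the T cell receptor complex, mRNA decay and antiproliferative genes, resting T cell genes, apoptosis and growth arrest, heat shock and stress, ribosome biogenesis, the cell cycle, the interferon response, reference housekeeping genes and markers of other cell types. Of 314 listed genes, 280 have a probe set that names them here and 243 passed the brightness filter. The others were not analysed here. A called probe set that is unnamed here may belong to a listed gene, and the list counts would then miss it.

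Each list was tested against the other genes with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation. With an estimated correlation camera uses the 3 residual degrees of freedom of the fit, so few lists can pass whatever their correlation. Each list was also tested with fry, which asks whether its genes move one way on balance or in either direction. Each of these p-values was adjusted over the 16 lists of a comparison. The overlap of the changes at 30 and 60 min, which share the 0 min samples, was set against 100 simulated series without any change. The fit was tested on simulated data in which 50 of the 29013 probe sets were changed at each of several fold sizes. For 60 min against 0 min it recovered 94.0% of the 4-fold changes, 40.0% of the 2-fold changes and 2.0% of the 1.5-fold changes, with 8 false calls. For 30 min against 0 min the shares were 84.0%, 38.0% and 4.0%, with 13 false calls, and for 60 min against 30 min they were 92.0%, 38.0% and 2.0%, with 12 false calls. The simulated samples varied independently, whereas real samples of 1 replicate number share part of their difference from the other. The shares and false calls may therefore not hold for the real data.

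The alternatives were quantile normalisation, scaling to a common 75th percentile, a floor at the 10th percentile in place of the offset, a larger offset, no filter, a stricter filter, the replicate number as a block, all 12 arrays with the RNA sample as a random block, each technical array alone, only the 2 groups compared, eBayes without trend, 1 probe set per gene, and leaving out each RNA sample. The correlation of the log2 signals of 2 arrays of the same RNA was 0.984 to 0.988, and the mean correlation with the arrays of the other replicate at that time 0.972 to 0.980. The median SD was 0.146 between arrays of the same RNA and 0.175 between replicates on the log2 scale. The ratio of 3′ to 5′ control signal was 1.03 to 1.33 for ACTB and 0.930 to 1.03 for GAPDH.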

Results

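The series asked how the transcripts of Jurkat T cells change in the first hour after a mitogenic stimulus, a phorbol ester with ionomycin. Transcript levels were read on 12 arrays from 6 RNA samples, with 2 biological replicates each at 0, 30 and 60 min and 2 arrays per RNA. After averaging the arrays of each RNA, 29013 probe sets for 12939 named genes were bright enough to test. In a principal component analysis the first component held 39.4% and the second 26.7% of the variance. Neither separated the times alone, since the replicates of each time also stood apart on both. Within each replicate number the times ran in order on both components. On the first they went from -7.10 to 46.33 in replicate 1 and from -39.88 to 5.09 in replicate 2. Replicate 1 lay higher on both components at each time.

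The comparison of 30 min with 0 min asked which transcripts move first. By their representative probe sets 12 genes rose, of which 5 belong to the 21 measured immediate-early transcription factors. EGR4, a zinc finger transcription factor, rose from a signal of 16.5 ± 20.9 (SD, n = 2) to 2600 ± 435 (SD, n = 2), a log2 change of 6.28 ± 0.33 (SE) with a limma adjusted p of 5.14e-04. FOS, which pairs with JUN proteins in the AP-1 transcription factor, rose by 5.60 ± 0.30 on the log2 scale (adjusted p = 5.34e-04), and both genes lay below the array median on all arrays at 0 min. DUSP2, a nuclear phosphatase that switches off MAP kinases, went from 465 ± 77.7 to 8563 ± 1110 (SD, n = 2), a 17.7-fold rise with an adjusted p of 9.87e-05. CD69, a surface receptor that marks recently activated T cells, rose 7.71-fold.

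In all, 19 probe sets rose and 0 fell in limma, against 546 higher and 387 lower at an unadjusted p under 0.05. Together the unadjusted counts are below the share of 0.05 of the 29013 tested that chance alone gives. Counts below that share mean that p-values ran high in this fit, so they are no sign for or against a wider response. With the replicate number as a block 75 probe sets rose and 0 fell in limma. The 19 probe sets stand for 15 named genes and the probe set 205249_at, which is unnamed here and rose by 5.66 on the log2 scale. No gene fell by its representative probe set. Besides the 4 above the genes that rose were SGK1, a serine/threonine kinase (7.33-fold), the AP-1 members JUNB (7.15-fold) and JUN (6.44-fold), IER2 (7.12-fold), NFKBIA, which encodes the inhibitor that holds NF-kappaB in the cytoplasm (6.75-fold), ZFP36, which promotes decay of mRNAs with AU-rich elements (3.40-fold), DUSP1 (2.81-fold) and the survival gene MCL1 (2.25-fold). Their adjusted p ran from 9.87e-05 for DUSP2 to 0.0274 for DUSP1, and each was higher in both replicates. Of their 11 further probe sets, all 11 lay in the same direction and 3 were called. EGR1, an early zinc finger transcription factor, was divided. Its brightest probe set, 201694_s_at, had a log2 change of 5.39 that did not pass (adjusted p = 0.0889), since the 0 min signal was 1176 in replicate 1 and 147 in replicate 2, while 201693_s_at rose by 5.50 (adjusted p = 9.87e-05). With the replicate number as a block 201694_s_at passed (limma adjusted p = 0.00380). Probe sets of CCNL1 and HNRNPA1 that do not represent their gene rose too, 1555827_at 3.91-fold and 222040_at 2.32-fold.

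Of the 21 measured immediate-early transcription factors 5 rose, namely EGR4, FOS, JUNB, IER2 and JUN, and 0 fell, with 10 rising when adjusted over the list alone. EGR3 stood 4.28 higher on the log2 scale without passing over all probe sets (adjusted p = 0.0531), but passed with the replicate number as a block (limma adjusted p = 0.00115). Of 18 feedback inhibitors 2 rose, DUSP2 and DUSP1, and the count was 2 adjusted over the list alone. Of 17 NF-kappaB genes 1 rose, NFKBIA, and 4 adjusted over the list alone. None of the 7 measured cytokine genes was called, against 2 adjusted over the list alone, and TNF stood 2.20 higher on the log2 scale (adjusted p = 0.158). TNF too passed with the block (limma adjusted p = 0.00345). The single members called in 3 other lists were CD69 among 10 activation receptors, ZFP36 among 14 mRNA decay genes and MCL1 among 16 apoptosis genes, and each of these counts was also 1 adjusted over the list alone. In the remaining 9 lists 0 members passed, although 1 of 14 heat shock and stress genes passed adjusted over the list alone.

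Against all other genes, camera at the preset correlation placed 6 lists higher at 30 min. These were the immediate-early genes (adjusted p = 2.12e-21), the NF-kappaB genes (9.66e-08), the cytokines (9.56e-06), the feedback inhibitors (7.15e-05), the mRNA decay genes (0.00234) and the apoptosis genes (0.0194). The mRNA decay genes had a median log2 change of 0.06 with 8 of 14 above 0. That of the apoptosis genes was 0.07 with 10 of 16 above 0. With 1 called member each, most genes of these lists moved little. With an estimated correlation none of them passed, at an adjusted p of 0.226 for the immediate-early, NF-kappaB and mRNA decay genes, an adjusted p of 0.285 for the cytokines and an adjusted p of 0.351 for the feedback inhibitors and apoptosis genes. Few degrees of freedom limit that test here. In fry no list passed for moving one way, the lowest adjusted p being 0.0556 for the mRNA decay genes. For change in either direction 6 lists passed, the feedback, activation receptor, mRNA decay and apoptosis lists at 0.00137, the immediate-early genes at 0.00225 and NF-kappaB at 0.00395. The markers of other cell types had a median log2 change of 0.16 with 10 of 13 above 0 (camera adjusted p = 0.0808). The count of 19 probe sets fell to 7 without 30 min replicate 1 and to 9 without 30 min replicate 2, when a lone sample was assumed to vary like the others. The calls of SGK1, JUNB, JUN, ZFP36, DUSP1 and MCL1 were each lost in at least 1 such fit, and those of SGK1, JUN, DUSP1 and MCL1 also without an intensity trend.

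**Figure D1:**
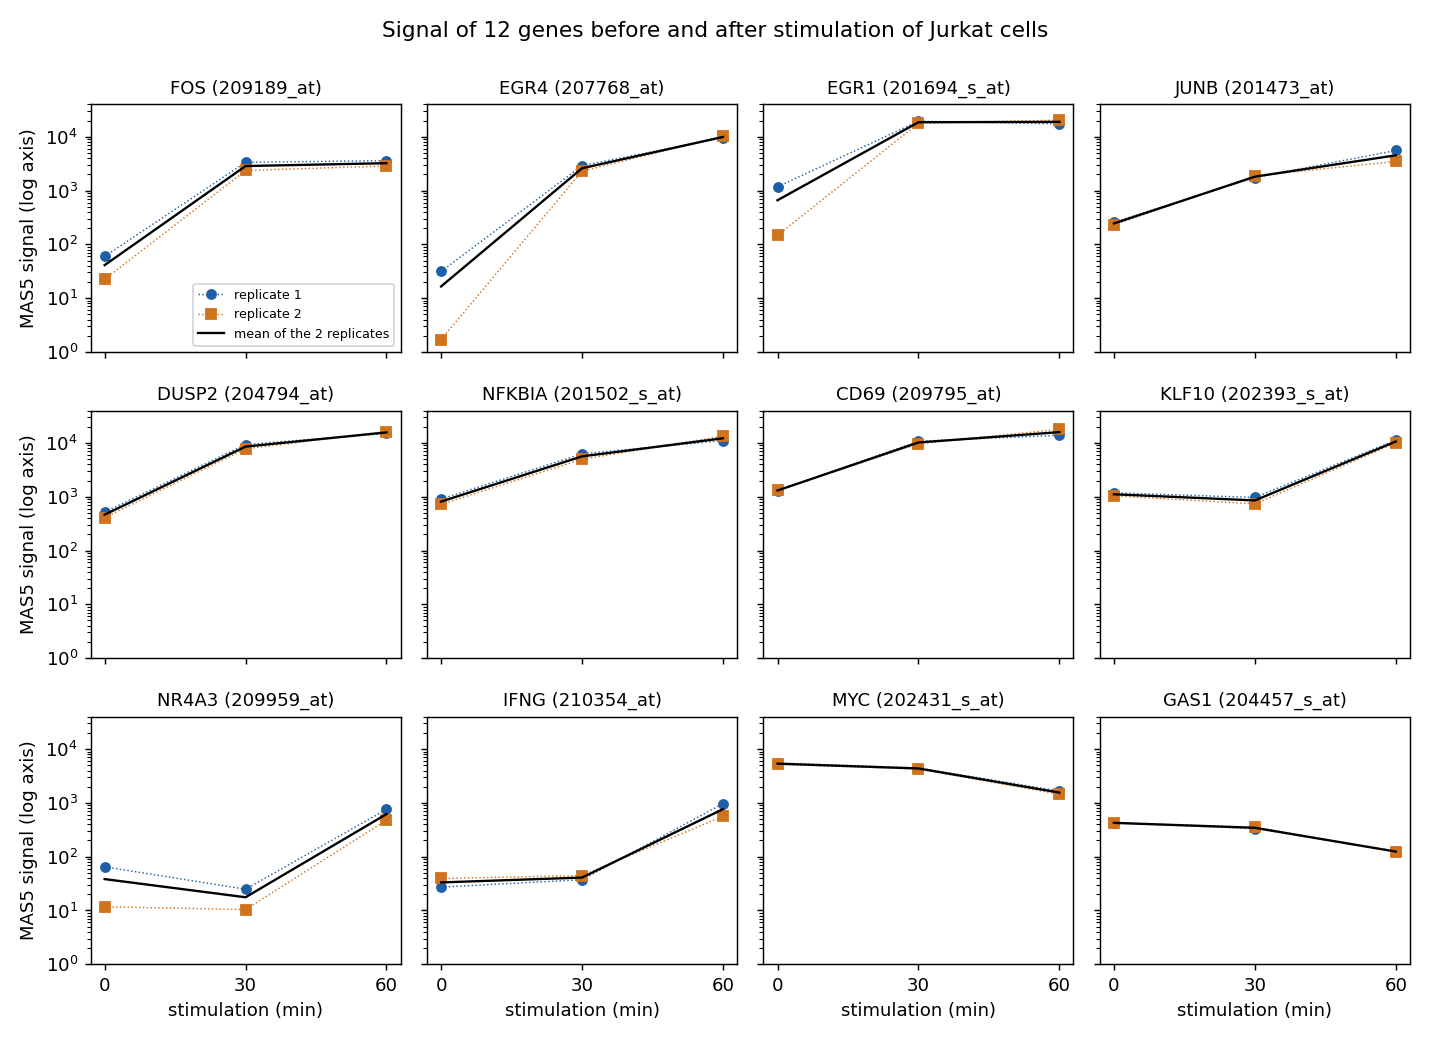
MAS5 signal on a log axis against minutes of stimulation for 12 genes, each by its representative probe set; points joined by dotted lines are the 2 replicates (mean of 2 arrays each) and the black line is their mean. FOS, EGR4, JUNB, DUSP2, NFKBIA and CD69 are already raised at 30 min, KLF10, NR4A3 and IFNG are raised at 60 min, MYC and GAS1 are lower at 60 min, and the 0 min signals of EGR1 lie apart at 1176 and 147.

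The comparison of 60 min with 0 min asked what the whole first hour changed. More genes were called than at 30 min, among them 9 of 17 NF-kappaB genes against 1 and 5 of 7 cytokine genes against 0. EGR4 went to 9939 ± 438 (SD, n = 2), a log2 change of 8.22 ± 0.33 (SE, adjusted p = 6.41e-05), the largest among the called probe sets. EGR3 rose by 5.92 ± 0.52, FOS by 5.78 ± 0.30, EGR1 by 5.41 ± 0.73, SGK1 by 5.17 ± 0.30 and DUSP2 by 5.03 ± 0.15 on the same scale. IFNG, the gene of interferon gamma, rose 14.2-fold from 33.2 ± 8.6 to 765 ± 286 (SD, n = 2). In the other direction MYC, a transcription factor that promotes growth, fell from 5367 ± 192 to 1556 ± 152 (SD, n = 2), a log2 change of -1.78 ± 0.12 with an adjusted p of 5.59e-04.

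In limma 181 probe sets rose and 24 fell, and by representative probe sets 92 genes rose and 18 fell. Among the rises 23 probe sets are unnamed here, and among the falls 3. The 12 largest named rises also held IER3 (20.5-fold), JUNB (17.3-fold), NFKBIA (14.7-fold), the orphan nuclear receptor NR4A3 (13.5-fold) and JUN (12.8-fold), with adjusted p from 1.01e-04 for NFKBIA to 0.00576 for NR4A3. That of EGR1 was 0.0203. EGR4, FOS, IFNG and, named further on, FOSB, TNF, CXCL8 and RELB had signals under the median of their array on all 4 arrays at 0 min, so their folds rest on the offset.

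In this fit the falls were smaller and fewer. How much fewer depends on the fit, since with the replicate number as a block 637 probe sets rose and 378 fell. PARS2, a mitochondrial prolyl-tRNA synthetase gene, had the largest at -2.79 ± 0.23 on the log2 scale, from 213 ± 18.8 to 13.3 ± 5.9 (SD, n = 2), and lay below the array median on every array at 60 min. After MYC came GAS1, a growth arrest-specific gene, at -1.63 ± 0.15. The sphingosine-1-phosphate receptor genes S1PR1, needed for T cells to leave lymphoid organs, and S1PR3 fell by 1.43 and by 1.12, S1PR1 to below the array median on every array at 60 min. PPP1R3B, RNF145, YAE1, ZNF235, BBS10, ZNF788P and CHD2 fell by between 1.24 and 0.99 on the log2 scale, with adjusted p from 0.0221 for BBS10 to 0.0444 for CHD2. CHD2 rests on 228999_at alone, as its 3 other probe sets had no lower value, and of the 2 other probe sets of PPP1R3B 1 was lower. All 205 called probe sets moved the same way in both replicates.

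Of the 21 immediate-early transcription factors 13 rose and 1, MYC, fell, and 19 rose and 1 fell adjusted over the list alone. EGR4, EGR3, FOS and EGR1 led them, and KLF10 (9.43-fold), FOSB (7.29-fold), ATF3 (5.13-fold) and MAFF (3.69-fold) were among the others. NR4A1, an early nuclear receptor, was not called by its representative probe set (log2 change 1.04, adjusted p = 0.436), whereas its probe sets 202340_x_at and 211143_x_at rose by 5.24 and 2.10. Of the 18 feedback inhibitors 6 rose, DUSP2, DUSP5 (7.42-fold), DUSP10, RGS16, DUSP1 and SPRY2, and 9 rose and 1 fell adjusted over the list alone. Of the 17 NF-kappaB genes 9 rose, and 14 adjusted over the list alone. They were led by IER3, NFKBIA, TNFAIP3, a deubiquitinating enzyme that restrains NF-kappaB (8.33-fold), and CD83 (7.93-fold), followed by NFKB2, RELB, NFKBID, REL and NFKBIE. Of the 7 cytokine genes 5 rose, IFNG, TNF (8.90-fold), LTB (7.68-fold), CXCL8 (7.16-fold) and TNFSF9 (2.38-fold), and the count was 5 adjusted over the list alone. IL13 (log2 change 0.44) and TGFB1 (0.13) did not pass.

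The mRNA decay list had 3 rises among 14 genes, ZFP36 (6.48-fold), its relative ZFP36L1 (3.11-fold) and BTG3 (2.04-fold), with 6 rises and 1 fall adjusted over the list alone. Among 16 apoptosis and growth arrest genes MCL1 (3.47-fold) and the cell cycle inhibitor CDKN1A (3.66-fold) rose, and 4 adjusted over the list alone. CD69 (11.9-fold) rose alone among the 10 activation receptors, also when adjusted over the list alone. In the resting T cell list S1PR1 fell and the 19 other genes did not pass, with 1 rise and 4 falls adjusted over the list alone. ID1 (log2 change -0.82) and TXNIP (-0.76) were the next lowest.

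Lists without a called member were the calcineurin and NFAT axis (0 of 16), the T cell receptor complex (0 of 18), heat shock and stress (0 of 14), ribosome biogenesis (0 of 18), the cell cycle (0 of 21), the interferon response (0 of 9), housekeeping genes (0 of 11) and markers of other cell types (0 of 13). Adjusted over the list alone, the counts were 2 rises in the T cell receptor complex, 1 in heat shock and stress, 2 in the cell cycle and 0 in the other 5. At an unadjusted p under 0.05 in limma, 1618 probe sets were higher and 1155 lower, together above the share of 0.05 of the 29013 tested that chance alone gives. RCAN1, a calcineurin regulator, stood at -0.20 and GAPDH at -0.13 on the log2 scale.

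Camera at the preset correlation placed 9 lists higher at 60 min and 1 lower. The adjusted p was 3.61e-34 for the immediate-early genes, 2.42e-27 for NF-kappaB, 3.65e-12 for cytokines, 3.88e-11 for feedback inhibitors, 4.13e-04 for mRNA decay, 0.00128 for apoptosis, 0.00879 for activation receptors, 0.0337 for the cell cycle, 0.0496 for markers of other cell types (these calls were lost under 4 and 12 of the 19 alternatives) and 0.00248 for the resting T cell genes, the list that lay lower. With an estimated correlation none passed, a test limited by its 3 degrees of freedom. Lists with an estimated correlation under the preset 0.01 lost their call too, such as the resting T cell (-0.009) and mRNA decay genes (-0.049). For such lists the loss is therefore no sign that correlation between genes made the call. The estimate was 0.449 for the immediate-early genes, 0.470 for feedback inhibitors and 0.371 for cytokines, far above the preset. For these lists the p-values at the preset correlation may be far too small. The adjusted p with an estimated correlation was 0.0894 for NF-kappaB, 0.107 for the immediate-early, cytokine and mRNA decay genes, 0.121 for the resting T cell genes, 0.198 for feedback inhibitors, apoptosis, cell cycle and markers, and 0.210 for activation receptors. Fry, which does not compare a list with other genes, gave an adjusted p of 0.00365 for the NF-kappaB and mRNA decay genes and 0.00969 for the immediate-early and cytokine genes moving one way, and 6 other lists passed at 0.0348 to 0.0397. For change in either direction 10 lists passed, from 2.20e-04 for mRNA decay to 0.0347 for ribosome biogenesis. The markers of other cell types moved with these lists, with a median log2 change of 0.21 and 11 of 13 above 0. The mRNA decay list had a median of 0.05 with a mean of 0.46, so part of its genes carried its call. The T cell receptor list had a median of -0.01 with a mean of 0.06, and the calcineurin list a median of 0.003 with a mean of -0.02.

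**Figure D2:**
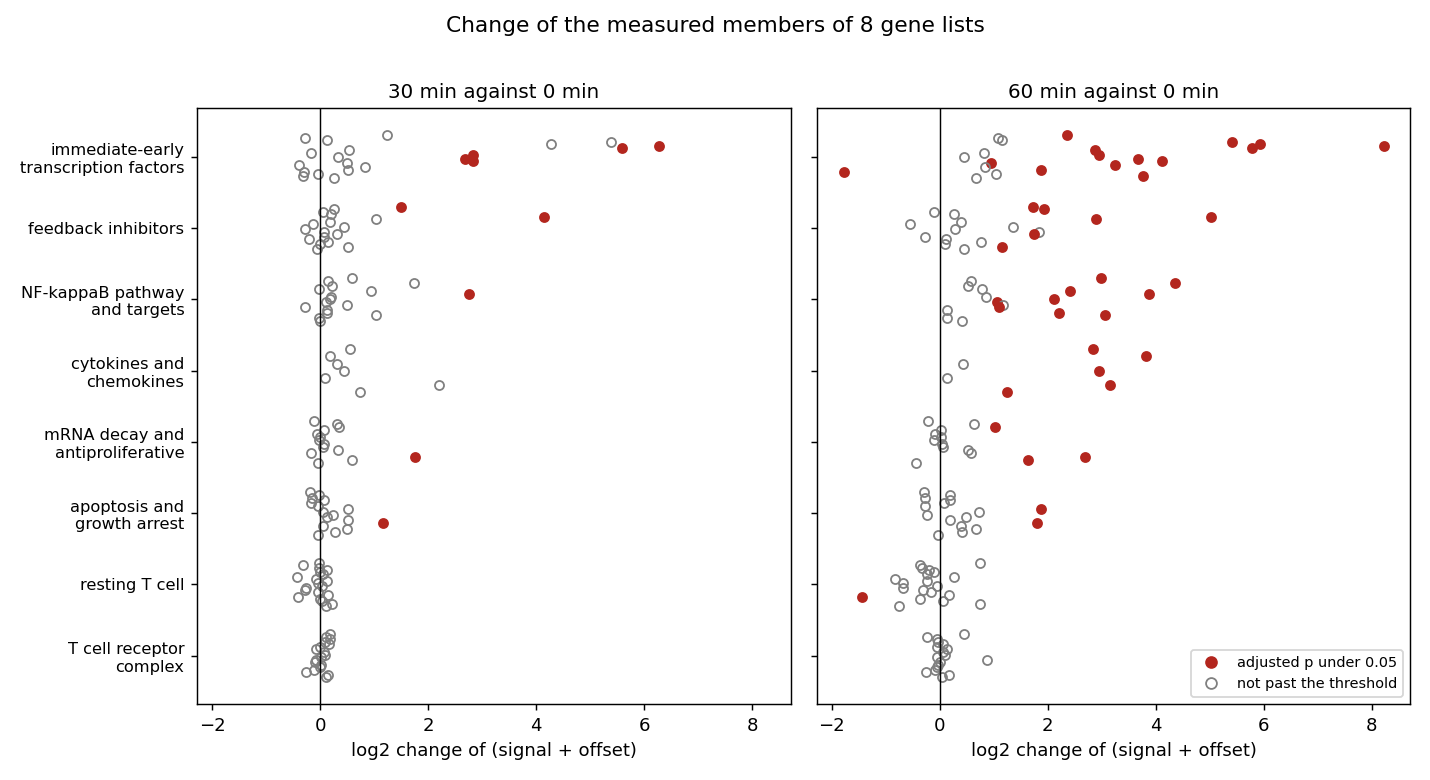
Log2 change of signal plus offset (horizontal axes) for each measured member of 8 gene lists (rows, 1 point per gene), at 30 min on the left and 60 min on the right, both against 0 min; filled points passed a limma adjusted p under 0.05 and open points did not. Among the immediate-early genes 5 are filled at 30 min and 14 at 60 min, 1 of them below 0, and the NF-kappaB list goes from 1 to 9 filled points while none is filled for the T cell receptor complex.

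With 1 sample left out the 205 probe sets became 68 without 0 min replicate 2, 88 without 60 min replicate 1, 100 without 0 min replicate 1, 116 without 30 min replicate 2 and 120 without 30 min replicate 1. EGR4, EGR3, FOS, SGK1, DUSP2, IER3, JUNB, NFKBIA, IFNG, JUN, PARS2, MYC and GAS1 passed under every alternative that tested them, whereas the calls of EGR1, NR4A3 and the 9 smaller named falls were each lost under at least 1.

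The comparison of 60 min with 30 min asked what came in the later part of the hour. The genes that rose in this interval included several with no called change at 30 min. NR4A3 went from 17.6 ± 10.2 to 620 ± 201 (SD, n = 2), a log2 change of 4.07 ± 0.39 (SE, adjusted p = 0.0140). IFNG rose by 3.64 ± 0.28 (adjusted p = 0.00475), and KLF10, a zinc finger gene of the early response, by 3.62 ± 0.16 (adjusted p = 5.75e-04), from 854 ± 166 to 10656 ± 878 (SD, n = 2). At 30 min these 3 genes had log2 changes of -0.31, 0.19 and -0.38 against 0 min, none called. MYC (-1.48 ± 0.12), GAS1 (-1.34 ± 0.15) and PARS2 (-1.82 ± 0.23) fell.

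In all, 44 probe sets rose and 4 fell, with 24 genes up and 3 down by representative probe sets, and all 48 moved the same way in both replicates. The other large rises were MIR146A, the host transcript of a microRNA that targets NF-kappaB signalling (6.90-fold), CRTAM, a surface receptor of activated T cells (6.14-fold), IER3 (6.13-fold), CD83 (5.25-fold), SGK1 (4.90-fold), the chemokine gene CXCL8 (4.85-fold), RELB (4.22-fold), TNFAIP3 (4.06-fold) and NFKBID (3.80-fold). Their adjusted p ran from 0.00352 for CD83 and NFKBID to 0.0388 for SGK1. IFNG, MIR146A, CRTAM and CXCL8 lay below the array median on all arrays at 0 and 30 min and NR4A3 on all arrays at 30 min, so their folds rest on the offset. The probe set 244447_at, unnamed here, had the largest rise of the comparison at 4.68 on the log2 scale.

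Of the 17 NF-kappaB genes 6 rose between 30 and 60 min, IER3, CD83, RELB, TNFAIP3, NFKBID and REL, and 12 adjusted over the list alone. Of the 21 immediate-early genes 2 rose (NR4A3 and KLF10) and MYC fell, with 15 rises and 1 fall adjusted over the list alone. IFNG and CXCL8 rose among the 7 cytokines, 5 adjusted over the list alone, and DUSP10 among the 18 feedback inhibitors, 9 adjusted over the list alone. The other 12 lists had 0 called members in limma by representative probe sets. Adjusted over the list alone, 4 mRNA decay genes rose and 1 fell, 2 resting T cell genes rose and 4 fell, 3 apoptosis genes rose, 1 activation receptor and 1 T cell receptor gene rose, and the other 7 lists had 0. Unadjusted, 1019 probe sets were higher and 795 lower at p under 0.05 in limma, together above the share of 0.05 of the 29013 tested that chance alone gives.

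Camera at the preset correlation gave an adjusted p of 7.74e-26 for NF-kappaB, 5.47e-17 for the immediate-early genes, 4.98e-09 for cytokines, 8.72e-09 for feedback inhibitors, 0.00576 for mRNA decay and for the resting T cell genes (lower), and 0.0119 for apoptosis. With an estimated correlation the adjusted p was 0.0955 for NF-kappaB, 0.182 for cytokines, mRNA decay and resting T cell genes, 0.185 for the immediate-early genes, 0.318 for feedback inhibitors and 0.344 for apoptosis, so no list passed. That test was limited by few degrees of freedom, as before. Fry gave an adjusted p of 0.0181 for NF-kappaB, 0.0261 for mRNA decay and 0.0345 for cytokines moving one way, and of 0.147 for the immediate-early genes, while 7 lists passed for change in either direction, from 4.79e-06 for mRNA decay to 0.0339 for feedback inhibitors. The markers of other cell types had a median log2 change of 0.09 with 7 of 13 above 0, and the mRNA decay genes one of 0.02 with 8 of 14 above 0. The 48 probe sets became 2 without 30 min replicate 2, 4 without 30 min replicate 1, 10 without 60 min replicate 1 and 28 without 60 min replicate 2. KLF10 passed in every fit, and the calls of the 14 other named genes were each lost in at least 1.

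Of the 19 probe sets that changed by 30 min, 18 were also changed at 60 min against 0 min, all but 222040_at of HNRNPA1. Between 30 and 60 min 3 of the 19 rose further, SGK1 and probe sets of EGR4 (207767_s_at) and MCL1 (200798_x_at), 0 fell back by the test, and 17 were higher by value at 60 min. FOS (log2 change 0.19 from 30 to 60 min), IER2 (0.12) and EGR1 (0.02) were near their 30 min level, with no change called. For CCNL1 1555827_at and HNRNPA1 222040_at the signal was lower at 60 than at 30 min by value, with adjusted p of 0.131 and 0.165. Of the 181 probe sets that rose by 60 min, 164 were above 0 min by value at 30 min, and of the 24 that fell, 23 were below. All 48 probe sets that changed between 30 and 60 min were also changed at 60 min against 0 min.

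Since both comparisons use the same 0 min samples, part of this overlap may come from them. Simulated groups without any change shared 0.010 rises on average and at most 1, and independent lists of these sizes would share 0.118, against the 18 observed. Neither value measures how much of the 18 comes from the shared samples. Over all probe sets, which are not independent, the fold changes at 30 and 60 min correlated at 0.624 against 0.501 in the simulation, with a covariance of 0.0516 against 0.0320. With 2 samples at 0 min a split would leave each comparison a single one, and none was made.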

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

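The rule of this part, Dixon's test, was set before the values were seen, but the array measures it was applied to were chosen after the values of the arrays had been seen. One array stood apart from the others of its time in a measure of array quality: the median signal of the first array of 30 min replicate 2 was 76.69, and the other 3 arrays at 30 min lay between 84.04 and 84.81. Its gap to the nearest array, as a share of the range of the 4 arrays, exceeded Dixon's 95% critical value. Chance gives about 1 such array in 20 groups of this size, and 12 groups of values were looked at. EGR4, FOS, DUSP2 and the other 9 genes that rose at 30 min did so in both replicates.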

How the results depend on the processing

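No named result turned direction under any of the 19 alternatives, and 20 of the 51 named results passed the threshold under every setting that tested them. The count of changed probe sets at 30 min (19 as reported) became 75 with the replicate number as a block, 78 with all 12 arrays and the RNA sample as a random block, 12 with eBayes without trend, and 7 to 21 when 1 RNA sample was left out. At 60 min (205) it became 121 without the filter, 1015 with the replicate block, 737 with the random block, 128 with technical array 2 only, 121 with only the 2 groups compared, 111 without trend, 131 with 1 probe set per gene and 68 to 145 with 1 sample left out. Between 30 and 60 min (48) it became 19 without the filter, 382 with the replicate block, 305 with the random block, 19 with technical array 2 only, 19 without trend and 2 to 39 with 1 sample left out. The probe sets changed by 30 min that changed again by 60 min (3) became 6 with quantile normalisation, 0 without the filter, 34 with the replicate block, 38 with the random block, 5 with technical array 1 only, 0 with array 2 only, 0 without trend and 0 to 5 with 1 sample left out. The random block treats 12 arrays as partly independent. For the other alternatives the cause was not tested. The camera lists called at the preset correlation (23 of 48 tests) stayed between 19 and 26. The markers of other cell types at 60 min lost their call under 12 alternatives, the cell cycle genes at 60 min under 4, the apoptosis genes under 3 at 30 min and 2 between 30 and 60 min, the resting T cell genes under 2 between 30 and 60 min, and the mRNA decay genes at 30 min and between 30 and 60 min and the activation receptors at 60 min under 1 each.

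The labels give replicate numbers 1 and 2 at each time, and the titles carry 1 further number for the samples of replicate 1 and another for those of replicate 2, but no label says that either marks a shared culture or day. Differences between replicate 1 and 2 correlated at 0.381, 0.399 and 0.358 between pairs of times. Samples of the same replicate number thus shared part of their difference from the other replicate, whatever the number marks. The reported fit has no term for this shared part and counts it as scatter between replicates, whereas the replicate block takes it out. These correlations were weighed after the counts with the block had been seen. Each comparison holds only 2 such pairs and no label states a pairing, so the fit without the block was kept as the reported one. Its counts of calls therefore depend on leaving the shared part in. With the replicate block, 637 probe sets rose and 378 fell at 60 min, against 181 and 24. At 30 min the block brings calls for EGR1 (adjusted p = 0.00380, against 0.0889 as reported), EGR3 (0.00115 against 0.0531), TNF (0.00345 against 0.158), IER3 and TNFAIP3. With the block TAGAP and PMS2P5 were called as risen at 30 min (3.02e-04 and 0.0260) and as lower at 60 than at 30 min (0.0122 and 0.0166). Dim genes are limited by scatter in MAS5 values near background, and a floor in place of the offset gave 182 probe sets at 60 min.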

Other observations

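In this part, the tests on EGR1, on the ZNF genes and on the T cell receptor genes were chosen after the values were seen, the other tests on the hypoxia genes after the first such genes were seen but before the genes tested were looked at, and the bootstrap intervals of the hypoxia genes, the markers and the ZNF count were added after these values were seen. Several called rises at 60 min fall outside the fixed lists and the largest 12, and were picked from the table after their values were seen. The regulators of the eIF2alpha phosphatase PPP1R15A (log2 change 2.58, adjusted p = 4.04e-04 in limma) and PPP1R15B (0.70, adjusted p = 0.0323) both rose. So did the glucose transporter gene SLC2A3 (2.17, adjusted p = 0.00236), the endoplasmic reticulum stress gene HERPUD1 (1.12), the T helper lineage factor GATA3 (1.08), IL23A (1.33), CXCL3 (1.88) and MAP3K14, a kinase of the non-canonical NF-kappaB pathway (1.45). IDH1 (-0.75), RHOH (-0.79) and RRAGD (-0.70) fell.

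By a log2 increase over 1 and an unadjusted p under 0.01 in both steps, 11 probe sets were highest at 30 min, and those given here were chosen after their values were seen. TAGAP, by its representative probe set, went from 1242 to 2947 and 1906 (adjusted p = 0.0889 and 0.434 in limma). In the next genes another probe set was not highest at 30 min. For CCNL1, a cyclin linked to splicing, 1555827_at went from 96.8 to 439 and then 222, whereas 220046_s_at went from 2521 to 5015 and 6148. For HNRNPA1, a splicing regulator, 222040_at went from 651 to 1541 and 960, while 221919_at went from 730 to 1398 and 1488. Neither later decrease passed (adjusted p = 0.131 and 0.165 in limma), and what part of a transcript each probe set reads was not analysed here.

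Genes of the hypoxia response were higher in replicate 1 than in replicate 2 at all 3 times, by 1.40-fold (VEGFA) to 8.83-fold (MIR210HG) on average for the 11 seen first, with a median of 3.67-fold. A further 19 genes chosen by name had a median log2 difference of 0.694 (bootstrap 95% interval 0.533 to 0.771), above the 0.0505 that 95% of 10000 random lists of like brightness stayed under, which argues against a general shift between the arrays. The 8 of these brighter than 5000 in replicate 2 would need a median foreign share of 16.9% even at the highest signal of any array, a log2 loss of 0.267 in T cell receptor genes, which differed by -0.0096 (bootstrap 95% interval -0.111 to 0.158), and this argues against cells without T cell receptor transcripts as their source. For the dimmer genes another cell type stays open, since its markers gave 0.154 (bootstrap 95% interval -0.099 to 0.221) against a bound of 0.178. A different oxygen or nutrient state of the cultures, which no label describes, may account for the pattern as a hypothesis. It predicts that most of the 19 genes are higher at each time, and 89.5% were. Any other difference shared by the replicate 1 samples that raises these genes would give the same, so this share cannot tell them apart.

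At 0 min EGR1 read 1176 in replicate 1 and 147 in replicate 2. If stimulated RNA had been mixed in, EGR1 would need 5.95% of the 60 min signal, whereas 38 other risen genes brighter than 2000 gave a median of 2.77% (bootstrap 95% interval 1.34 to 5.36), with single genes from -23.6% (PTPN7) to 23.4% (SAT1) and 12 of the 38 at or above EGR1. Among those with the largest named rises at 60 min, the share was 0.31% for EGR4, 0.51% for JUNB, 0.75% for DUSP2 and 1.04% for FOS. It was 1.34% for SGK1, 1.78% for NFKBIA, 2.51% for EGR3, 3.03% for IER3 and 5.13% for JUN, each below EGR1. The limit of 2000 was set after values were seen, the interval ends close to the EGR1 value, and 201693_s_at was 208 against 118, so a smaller admixture stays open. Early-response genes in that culture may have been partly active, since 17 of 20 other immediate-early genes were higher in replicate 1, with a median of 0.624 against a bound of 0.122 in random lists. The median was 0.300 at 30 min and 0.183 at 60 min. Stimulated RNA mixed into the 0 min sample would raise these genes too, so their difference cannot tell it from partial activation.

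Zinc finger genes with a ZNF symbol made up 3 of the 18 genes that fell at 60 min, against 366 of 12939 measured (Fisher's exact test, two-sided, p = 0.0134). The set was chosen after these falls were seen, so this p-value restates the observation and is no support for it. These 3 were ZNF235, ZNF788P and ZNF23. The call of ZNF235 was lost under 11 of 18 alternatives and that of ZNF788P under 10 of 19. At an unadjusted p under 0.05 in limma 45 were lower (bootstrap 95% interval 33 to 58), above the 24 that bounds 95% of random lists of like brightness. Low signal alone thus gave fewer falls in those lists. But the 45 include the falls for which the set was picked, which favoured this outcome, so low signal is not excluded. Their median change against other genes was -0.0517 as deposited and -0.0735 (bootstrap 95% interval -0.0986 to -0.0461) with quantile normalisation, which argues against the scaling. The random lists and the bootstrap intervals take genes as independent, which was not tested. The set was first viewed under a wider symbol pattern, 26 ZNF genes were higher at the unadjusted threshold, and no biological explanation was tested.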
